A study of Mus musculus with 36 samples.

How the data were processed

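The series holds 36 spotted 2-colour cDNA arrays of mouse lung, 4 at each of 9 time points. Per the labels' protocols, each array compared a pool of RNA from 5 hypoxic mice with a pool from 5 time-matched controls, the cDNA was made with Superscript II, and slides were scanned on a GenePix 4000A scanner and read with GenePix Pro 4.0. Per the labels, the authors deposited log2 ratios that were background corrected, had poor spots removed and were normalised by lowess. The deposited log2 values were used as they stand, with removed spots left empty. The array medians lay between -0.016 and 0.050 and the array SDs between 0.17 and 0.52, so the arrays were centred near 0 but not set to a common spread. The protocol names the hypoxic sample and Cy5 first and the control and Cy3 second, which makes a positive value likely to mean higher in hypoxic lung. No label records a dye swap. The channel intensities, and so signal over background, were not used here.

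Spots were named through the platform annotation. Of 15388 spots, 9598 had 1 gene symbol, 514 had several and 5276 had none. Entrez identifiers of 9510 of the named spots matched the RefSeq gene table of GRCm38.p6, used for names and gene spans alone, and no symbol changed. Spots of a gene were averaged on each array (6971 genes, 1880 of them with over 1 spot), and spots with several symbols or none were kept as unnamed features, giving 12761 features.

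Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, testing changes in either direction, with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Since the labels describe a single pool per condition and day, the day was the unit for the phases: arrays of a day were averaged, and 9 time-point means (5 hypoxia, 4 recovery) were fitted with a mean per phase, their difference, or a slope on log2 day within each phase. A feature needed values on at least 2 arrays at each day, which left 12159. Single days, and days 22 and 35 against day 21, were fitted on the 36 arrays with a mean per day and a shared estimate of the spread, for features with at least 3 of 4 arrays. Nothing in the labels says that the 4 arrays of a day came from separate mice, so those p-values measure only the spread between arrays, which may be technical.

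Gene lists (25) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 measured genes (21) were tested with cameraPR at a preset correlation of 0.01, adjusted over 63 tests for the phases and 189 for the days, and again with an estimated correlation. At single days the estimated correlation was limited to members with a value on all arrays. The lists for alveolar type I epithelium, T and B lymphocytes, MHC class II and adipose tissue had 2, 3, 3 and 3 measured genes and were not tested. Of their members, Krt7 (0.46), H2-DMa (0.21) and Elovl3 (0.26) were higher over the hypoxia phase and Lpl (-0.60) and Pnpla2 (-0.26) lower, and Ighm (0.08) and Blnk (0.18) did not pass. In replicates 1 and 2 alone H2-DMa (adjusted p = 0.063) and Pnpla2 (adjusted p = 0.23) did not pass.

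Named genes have 1 symbol that is not a placeholder. They are the largest changes past the threshold with a single sign: up to 12 in each direction for the hypoxia phase (all 5 time points), up to 8 for recovery (all 4), up to 10 for the difference (separate ranges) and up to 5 for each trend. For days 22 and 35 against 21 they are up to 5 (arrays that do not overlap), and for each day up to 3 (all arrays). Where fewer than 6, 4, 5 or 2 qualified for the phases, their difference or the trends, the lowest p filled the set, and such genes are said not to pass. Up to 4 members of each list that passed in a phase comparison, or else up to 2 with the lowest p, and 13 genes chosen for hypoxia, pulmonary vessels and lung cells were added where measured. Among called features of the hypoxia phase, 81 with placeholder symbols were passed over. The 9 genes plotted by day were picked from the named ones after their values were seen.

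The fits were tested on simulated data for 7556 genes. Of 100 genes changed by 0.5 on the log2 scale, 88 percent were recovered at a single day, 64 percent between days 22 and 21, 99 percent over the hypoxia phase and 91 percent between phases. Of 100 changed by 1, 99 percent, 92 percent, 100 percent and 99 percent were recovered, none in the wrong direction. Calls of unchanged genes were 13 of 200 at a single day, 5 of 161 between days 22 and 21, 12 of 211 over the hypoxia phase and 11 of 201 between phases. For lists, 1 raised list among 21 was called and none of the unchanged lists was. This does not show how the list test behaves at the correlations estimated in the real lists over the phases, up to 0.48. None of the 12 list calls over the phases held with an estimated correlation.

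The alternatives were median centring, scaling to a common spread, other limits on missing values, each spot on its own, robust eBayes, a 1.5-fold threshold, the replicate number as a block, the arrays of a day alone, medians of a day's arrays, all arrays with the day as a random block, another time scale, other list tests, and each array or time point left out. A term for replicates 1 and 2 against 3 and 4, fits on either pair, and list tests and the share kept in recovery without replicate 1 of day 28, were added after seeing the data.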

Results

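Whole lungs of BALB/c mice were compared with lungs of time-matched control mice on spotted 2-colour cDNA arrays, in which both RNA samples are labelled with different dyes and hybridised to the same glass slide. Mice were held at 0.5 atm for 1, 3, 7, 14 or 21 days, or for 21 days followed by 1, 3, 7 or 14 days back at sea-level pressure, here called days 22, 24, 28 and 35. Each of the 9 time points had 4 arrays, 36 in all, and each RNA was a pool from 5 mice. The arrays held values for 14186 to 15042 of 15388 spots, and the number of arrays limits the precision. Every value is a log2 ratio, and a positive value is taken as higher in the lung exposed to hypoxia. That direction is likely rather than certain, because it rests on the order in which the protocol names the samples and the dyes.

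The arrays of a day correlated with a median Pearson r of 0.41 across genes, which are not independent replicates. That median was lowest at day 22 (-0.12) and day 21 (0.11), against 0.62 at day 28. Replicates 1 and 2 of a day, or 3 and 4, correlated with a median r of 0.69, whereas arrays taken across these pairs had a median r of 0.29. At days 22 and 21 the median across the pairs was -0.15 and -0.04, and within them 0.64 and 0.58. The lowest correlation within a day was -0.25, between replicates 2 and 4 of day 22, so no array fell below -0.3 against another of its day. Among 288 pairs of arrays from different days taken across the replicate pairs, the median r was 0.12 and 3 lay below -0.3, the lowest at -0.32 between replicate 2 of day 3 and replicate 3 of day 22. Each day had its own control, so these arrays do not share a reference, and the direction stays likely rather than settled. Day means correlated with a median r of 0.70 between hypoxia days, 0.48 between a hypoxia and a recovery day, and 0.41 between recovery days. The most alike recovery days were 24 and 28 (r = 0.74), and the least alike were 28 and 35 (r = 0.23).

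The first comparison asked which genes differed from control lung over the whole of the hypoxia phase. Cdk19, a kinase of the Mediator complex, was the most strongly raised named gene, with a mean log2 ratio of 1.68 ± 0.18 (SD over time points, n = 5), a 3.21-fold rise. Several genes of the extracellular matrix also rose. Mfap4, a protein of elastic fibres, rose by 1.24 ± 0.61, from 0.17 at day 1 to 1.67 at day 3, and remained at 1.37 at day 21. Tnc, which encodes tenascin C, rose by 0.89 ± 0.09, and Col4a2, a basement membrane collagen chain, by 0.85 ± 0.10. Spon2 (0.99 ± 0.17), Pmepa1 (0.85 ± 0.23), Mgp (0.78 ± 0.38) and the chemokine Cxcl12 (0.76 ± 0.19) were also higher at all 5 hypoxia time points.

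Among named genes lower at all 5 time points, Tgfbr3, a co-receptor for transforming growth factor beta, had a mean of -1.39 ± 0.29, which is 0.38 of the control level. S100a9, a neutrophil gene, had a mean of -1.51 ± 1.45 (limma adjusted p = 0.038) but stood at 0.31 at day 1. Pdlim7 (-1.31 ± 0.53), the endothelial and myeloid lectin Cd93 (-1.29 ± 0.43), Bche, which encodes butyrylcholinesterase (-1.20 ± 0.46), and Irgq (-1.13 ± 0.51) were lower at all 5 time points. Igfbp3 (-1.07 ± 0.48), Ttc12 (-1.06 ± 0.52), Ampd3 (-1.02 ± 0.40), the thrombin receptor gene F2r (-0.96 ± 0.34), Pip4p1 (-0.96 ± 0.51) and Rex2 (-0.95 ± 0.45) completed the set. The limma adjusted p of these genes lay between 8.9e-05 for Tgfbr3 and 0.00071 for Pip4p1. In all, 5152 of 12159 genes or unnamed spots passed an adjusted p of 0.05, 3000 higher and 2152 lower, with a median absolute log2 ratio of 0.23. Of the 5104 with values in both replicate pairs, 4542 (89.0 percent) had the same sign in replicates 1 and 2 as in 3 and 4, against 56.6 percent of all features; the calls rest on the mean of both pairs, which favours a shared sign. Replicates 1 and 2 alone gave 4772, and replicates 3 and 4 alone gave 6286. Of 86 named genes called over this phase, 66 were called in each pair alone; Ampd3 was at -1.74 in replicates 1 and 2 and -0.30 in 3 and 4 (adjusted p = 0.15).

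Genes of the circadian clock were split by direction. Arntl, the core activator also known as BMAL1, rose by 1.13 ± 0.51 (SD, 5 time points). Nr1d2, a repressor of the clock, stood at -1.11 ± 0.34, and the clock output genes Tef and Per3 stood at -0.78 ± 0.19 and -0.63 ± 0.23. Of 12 measured members of the list, 3 rose and 5 fell, the same counts when adjusted over the list alone. The list as a whole did not pass (cameraPR adjusted p = 0.10).

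Smooth muscle contractile genes rose together: 8 of 11 measured members were higher and none was lower, or 9 higher when adjusted over the list alone. Myl6, a myosin light chain, rose by 0.45 ± 0.16 (0.77 in replicates 1 and 2, and 0.14 with adjusted p = 0.066 in 3 and 4), the actin cross-linker Flna by 0.42 ± 0.27 (its spots at 0.67 and 0.16), Cald1 by 0.38 ± 0.08 and Cnn2 by 0.34 ± 0.10. The list passed with the preset correlation (adjusted p = 0.00099) and not with an estimated correlation (adjusted p = 0.73). In the extracellular matrix list, 15 of 28 members rose and 3 fell, with the same counts adjusted over the list alone; the small proteoglycan Dcn was among those lower, at -0.84 ± 0.27. That list passed at adjusted p = 0.018, against adjusted p = 0.73 with an estimated correlation. Cell cycle genes gave 25 higher and 3 lower of 44, or 29 and 3 adjusted over the list alone. Ccnb2 (0.50 ± 0.30), Cdk1 (0.50 ± 0.33) and the DNA ligase gene Lig1 (0.40 ± 0.22) rose, whereas Aurkb stood at -0.36 ± 0.43 and passed in neither replicate pair alone (adjusted p = 0.080 and 0.087). The cell cycle list passed at adjusted p = 0.00091, and had an adjusted p = 0.73 with an estimated correlation.

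Genes studied in pulmonary hypertension were lower as a list (adjusted p = 0.0018; adjusted p = 0.73 with an estimated correlation). Of 29 measured, 11 fell and 3 rose, the same counts adjusted over the list alone. Bmpr2, the bone morphogenetic protein receptor mutated in heritable pulmonary arterial hypertension, stood at -0.87 ± 0.25 and was lowest at day 7, at -1.16. The endothelin receptor gene Ednrb stood at -0.66 ± 0.22 and Id2, a target of bone morphogenetic protein signalling, at -0.43 ± 0.07. In the fibroblast and pericyte list 4 of 14 members rose, among them Col3a1 (0.71 ± 0.38) and Col1a1 (0.64 ± 0.43), and 5 fell (list adjusted p = 1.00). A single spot of the 4 for Col3a1 had a hypoxia mean of 0.08, and the others lay between 0.85 and 0.97. The erythroid list had 7 members higher and 1 lower of 15, with Hbb-b1 at 0.99 ± 0.46, Hba-x at 0.91 ± 0.41, Hbb-y at 0.67 ± 0.32 and the heme synthesis gene Alas2 at 0.63 ± 0.30 (list adjusted p = 0.30). The hemoglobin spots, 29 in all, moved together over the time points, and 22 spots were listed under several genes that include a hemoglobin gene. The hemoglobin members may therefore share 1 signal and were not told apart. A spot named Phtf1, at 1.04 ± 0.41, followed the hemoglobin spots over the time points (r = 0.99).

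Among genes known to respond to hypoxia-inducible factor, 7 of 26 rose and 5 fell, or 8 and 6 adjusted over the list alone. The list did not pass (adjusted p = 0.86). Its test and its mean of -0.02 were negative while its median was 0.05. Hk1, a hexokinase, rose by 0.46 ± 0.19, and Tfrc (-0.40 ± 0.09; its 3 spots from -0.71 to -0.10) and Pfkfb3 (-0.39 ± 0.23; -0.27 with adjusted p = 0.091 in replicates 1 and 2) were lower. The glucose transporter gene Slc2a1 (0.01 ± 0.17), Hmox1 (0.08 ± 0.19) and Hif1a (-0.05 ± 0.06) did not pass. In glycolysis 5 of 12 genes rose and 1 fell, with Pkm at 0.60 ± 0.31, Pfkl at 0.33 ± 0.13 and Aldoa at 0.25 ± 0.17 (list adjusted p = 0.18). Aldoa was at 0.43 in replicates 1 and 2 and at 0.07 in 3 and 4 (adjusted p = 0.34). Vegfa, Edn1, Nos3, Epas1, Acta2, Sftpc and Scgb1a1 had no spot with a single symbol and were not analysed here.

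In the macrophage and monocyte list 3 of 9 members fell, Cybb (-0.62 ± 0.19), Fcgr3 (-0.33 ± 0.20) and Fcgr1 (-0.27 ± 0.15), and none rose (adjusted p = 0.069). Fcgr1 was at -0.52 in replicates 1 and 2 and at -0.04 in 3 and 4 (adjusted p = 0.60). Endothelial genes went both ways, with Emcn (0.66 ± 0.25), Gja4 (0.48 ± 0.20) and Cdh5 (0.27 ± 0.10) higher and Ednrb lower among 7 (adjusted p = 0.66). Gja4 was at 0.73 in replicates 1 and 2 and at 0.23 in 3 and 4 (adjusted p = 0.065). Their median was -0.02, with a mean of 0.09 and a positive test. In the airway list Aldh1a1 (-0.45 ± 0.05) and Dnah5 (-0.16 ± 0.07) were lower of 8 (adjusted p = 0.15). The direction of Dnah5 turned between the pairs, with -0.43 in replicates 1 and 2 and 0.10 in 3 and 4 (adjusted p = 0.20). For the alveolar type II list, Muc1 (0.37 ± 0.21) and Lpcat1 (0.29 ± 0.20) rose among 7 members (adjusted p = 0.65; Lpcat1 was at 0.11 with adjusted p = 0.18 in replicates 3 and 4), and the phosphate transporter gene Slc34a2 stood at -0.60 ± 0.33. Its 3 spots differed widely, with hypoxia means of 0.10, -1.60 and -0.31. The antioxidant list gave 7 lower and 2 higher of 23 (adjusted p = 0.11), with Nfe2l2 at -0.52 ± 0.15 and Cat at -0.39 ± 0.17. Inflammatory mediators (adjusted p = 0.94), interferon response (adjusted p = 0.97), immediate early (adjusted p = 0.53), and cardiac and skeletal muscle genes (adjusted p = 0.85) did not pass over the hypoxia phase, nor did the neutrophil list (adjusted p = 0.85), whose median was 0.17, mean -0.08 and test positive. Members of these lists that passed were Tap2 (0.30), Gadd45g (0.61), Selp (0.17) and Tnnt1 (0.13), which were higher, and Irf1 (-0.32), Rgs2 (-0.42), Ier3 (-0.30) and Cxcl1 (-0.25), which were lower, among others. In replicates 3 and 4 alone the direction of Cxcl1 (0.02, adjusted p = 0.85) and Tnnt1 (-0.05, adjusted p = 0.61) turned, and in replicates 1 and 2 alone Ier3 (-0.13, adjusted p = 0.23) and Selp (0.06, adjusted p = 0.71) did not pass. Heat shock genes had 2 of 23 higher and 6 lower (adjusted p = 0.35; median 0.01, mean -0.02 and a negative test). Oxidative phosphorylation genes had 11 of 47 higher and 4 lower (adjusted p = 0.87).

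**Figure D1:**
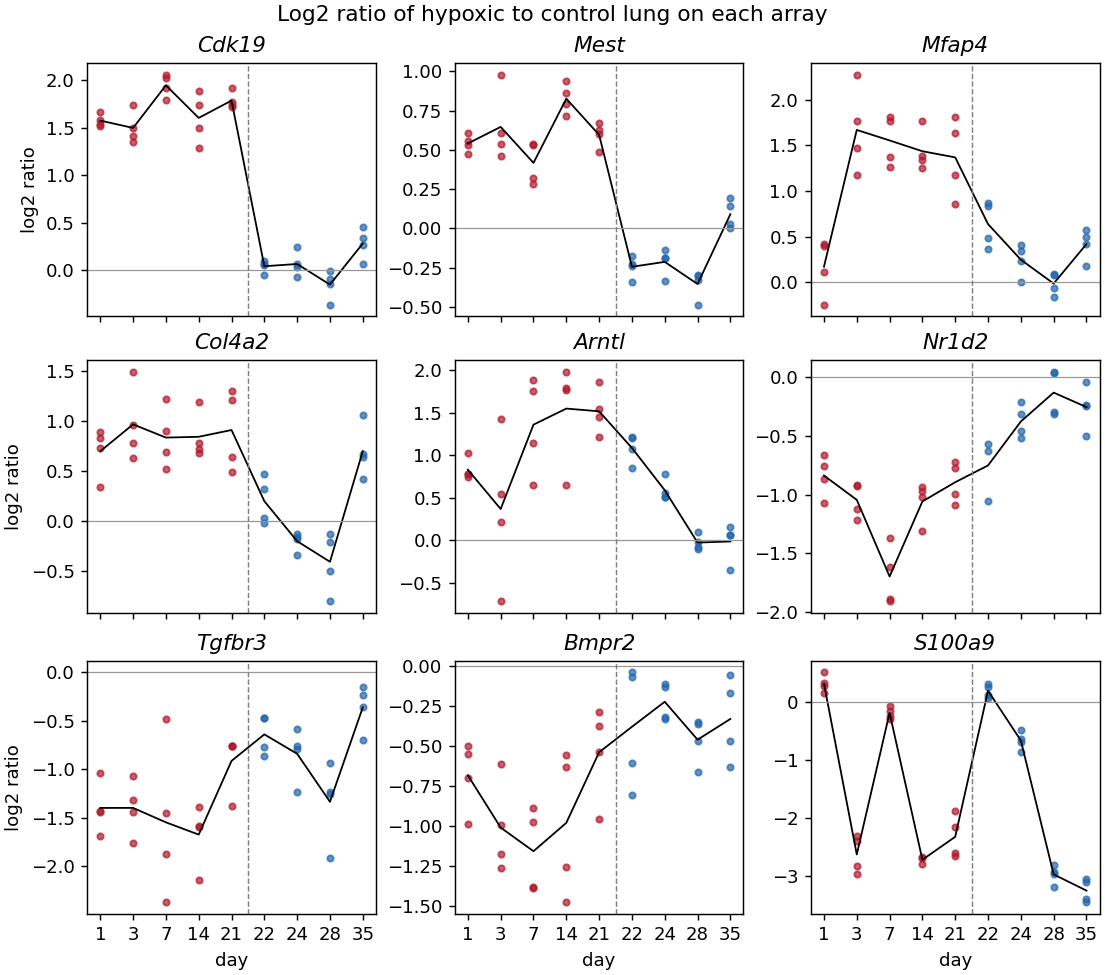
Log2 ratio of hypoxic to control lung (vertical axis) against day (horizontal axis, not to scale) for 9 genes; points are arrays, red for hypoxia and blue for recovery, and the line joins the means of 4 arrays. Cdk19 lies between 1.498 and 1.95 at the hypoxia days and between -0.15 and 0.28 at the recovery days, and S100a9 changes level from day to day in both phases.

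The second comparison asked which differences from control were present over the 14 days after return to sea-level pressure. Prnd, which encodes doppel, a relative of the prion protein, had the largest mean of the features that passed, 1.02 ± 0.91 (SD over time points, n = 4), with 1.29 at day 22 and 2.18 at day 35 but 0.22 at day 24. Emcn, a sialomucin of the endothelium, rose by 0.55 ± 0.42, the stress-response factor Atf3 by 0.55 ± 0.22 and the growth factor Mdk by 0.54 ± 0.13. Fxyd6 (0.40 ± 0.06), Zfand2a (0.38 ± 0.20), Rpl39 (0.37 ± 0.24) and Cmtm3 (0.35 ± 0.18) were higher at all 4 recovery time points. In replicates 1 and 2 alone Fxyd6 (0.41, adjusted p = 0.069), Cmtm3 (0.29, adjusted p = 0.096) and Tcn2 (-0.60, adjusted p = 0.075) did not pass. Tgfbr3 (-0.80 ± 0.41), F2r (-0.76 ± 0.51), Kctd10 (-0.64 ± 0.43), Sp100 (-0.61 ± 0.44), Cemip2 (-0.60 ± 0.16), Tcn2 (-0.60 ± 0.51), Srsf5 (-0.59 ± 0.26) and Aldh1b1 (-0.59 ± 0.26) were lower at all 4.

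In recovery, 580 of 12159 features passed, 201 higher and 379 lower, and the lowest limma adjusted p was 0.018. Of these, 142 higher and 321 lower features were also called in the same direction over the hypoxia phase, where independent lists of these sizes would share 49.6 and 67.1. The lists were not independent, because both phases shared 1 estimate of the spread for each feature. Features of low spread are favoured in both, so the excess is not a test of a lasting difference. Bmpr2 was lower at -0.35 ± 0.10 (adjusted p = 0.045), with -0.54 in replicates 1 and 2 (adjusted p = 0.017) and -0.16 in 3 and 4 (adjusted p = 0.22). Tef stood at -0.47 ± 0.18. Of 32 called genes that were named for recovery, for a list or among the chosen genes, 18 were called in each pair alone. The count depended on which days were used: it was 0 in limma without day 24 (2423 at an unadjusted p under 0.05), 2 without day 28, 12 without day 22 and 13 without day 3. Scaling all arrays to a common spread gave 3155 features, 1623 higher and 1532 lower, so that 51.4 percent were higher against 34.7 percent unscaled. Replicates 1 and 2 alone gave 1103 features, and replicates 3 and 4 alone gave 1609.

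Chaperones and genes of the unfolded protein response were lower as a list in recovery, with 7 of 23 lower and 1 higher, or 8 and 1 adjusted over the list alone (adjusted p = 0.0011; adjusted p = 0.73 with an estimated correlation). At day 35 the list was shifted up instead, with 8 higher and 1 lower (cameraPR adjusted p = 6.1e-16, or adjusted p = 0.084 with an estimated correlation). Hsp90b1, a chaperone of the endoplasmic reticulum, stood at -0.51 ± 0.32 and Dnajb9 at -0.42 ± 0.24 (adjusted p = 0.065 in replicates 1 and 2), whereas Bag3 rose by 0.39 ± 0.33. Oxidative phosphorylation genes shifted up as a list (adjusted p = 0.0058; adjusted p = 0.73 with an estimated correlation), with 4 higher and 2 lower of 47, or 13 and 3 adjusted over the list alone. Ndufa7 (-0.28 ± 0.05) and Ndufs1 (-0.19 ± 0.07) were its lower members. Ndufs1 passed in neither replicate pair alone (adjusted p = 0.069 and 0.13), and Ndufa7 was at -0.15 (adjusted p = 0.21) in replicates 1 and 2 and at -0.40 in 3 and 4. The other lists did not pass in recovery, with adjusted p from 0.13 for glycolysis to 0.85 for cardiac and skeletal muscle. Among them the endothelial list had a median of -0.07 and a mean of 0.03, the smooth muscle list a median of 0.02 and a mean of -0.03, and the cardiac and skeletal muscle list a median of -0.01 and a mean of 0.07. The day means of all features spread more widely at day 28 (SD 0.28) than at days 22, 24 and 35 (0.14, 0.15 and 0.16), and replicate 1 of day 28 had the largest SD of all arrays, 0.52.

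The third comparison subtracted the recovery phase from the hypoxia phase, to ask which differences from control were lost on return to sea-level pressure. Cdk19 fell from 1.68 to 0.06, a difference of 1.63 ± 0.10 (SE; limma adjusted p = 2.6e-05). Mest, an imprinted gene of the mesoderm, differed by 0.79 ± 0.10 (adjusted p = 0.023), Mfge8, a secreted protein that bridges phagocytes to dying cells, by 0.64 ± 0.09 and the alkaline phosphatase gene Alpl by 0.58 ± 0.08 (both adjusted p = 0.027). These 4 genes were the only features of 12159 to pass, all higher in hypoxia, and each lay above its recovery values at all 5 hypoxia days. Krt7 (0.62), Ivns1abp (-0.61), Ctla2a (-0.57), Ctla2b (-0.55), Smurf2 (-0.49) and Rnf141 (-0.48) also had separate ranges in the phases and did not pass.

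Smooth muscle contractile genes differed most as a list (median 0.36, adjusted p = 1.7e-08, or adjusted p = 0.73 with an estimated correlation), with none of 11 passing over all genes and 8 higher adjusted over the list alone. Extracellular matrix (median 0.22, adjusted p = 0.00017; 10 higher and 2 lower of 28 adjusted over the list alone) and glycolysis genes (median 0.21, adjusted p = 0.00017; 4 higher of 12 adjusted over the list alone) were also shifted toward hypoxia with the preset correlation, both with an adjusted p = 0.73 with an estimated correlation. Cell cycle genes shifted in the same direction (median 0.11, adjusted p = 0.00084), whereas pulmonary hypertension candidates (median -0.09, adjusted p = 0.010) and oxidative phosphorylation genes (median -0.07, adjusted p = 0.022) were lower in hypoxia than in recovery. None of the 12 list calls over the phases held with an estimated correlation, where the last 3 lists had an adjusted p = 0.73, or an adjusted p = 0.78 for oxidative phosphorylation. The lists not named here had an adjusted p from 0.15 to 0.62 for this difference. The count of 4 genes was 124 without day 21 and 1 without day 3, 22, 24 or 28, and became 800 when all 36 arrays were fitted with the day as a random block. Replicates 1 and 2 alone gave 34, and replicates 3 and 4 alone gave 2.

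**Figure D2:**
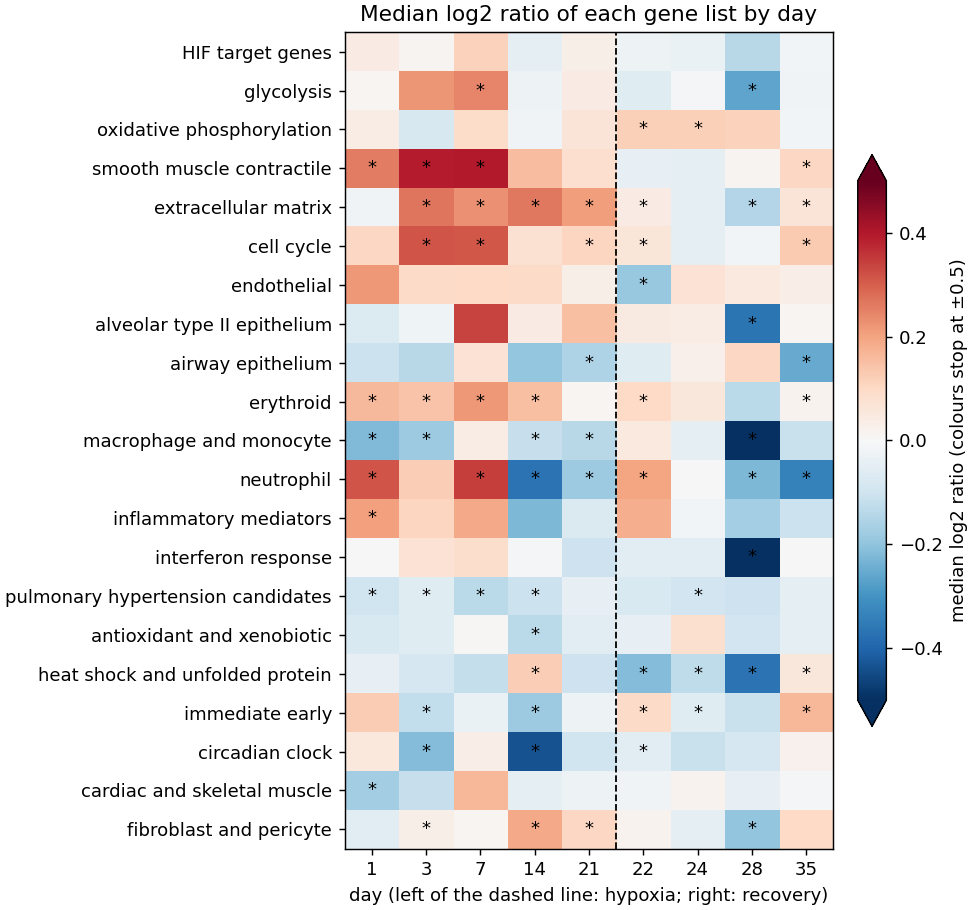
Median log2 ratio of each tested gene list down the side against day along the bottom; colour gives the median, and a star marks a list and day with a cameraPR adjusted p under 0.05 at the preset correlation. The smooth muscle contractile list is at 0.39 at day 3, and the interferon response list is at -0.74 at day 28.

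The first day after return was compared with the end of hypoxia. S100a9, a calcium-binding protein of neutrophils, was 2.51 ± 0.14 (SE) higher on the log2 scale at day 22 than at day 21. Prnd (0.95), Atf3 (0.85), Got2 (0.80) and Hbb-b1 (0.79) were also higher at day 22, and the Got2 spot followed the hemoglobin spots (r = 0.99). Cdk19 was lower by -1.75 ± 0.11, with Mest (-0.84), Amotl2 (-0.84), Cxcl12 (-0.77) and Emcn (-0.76) also lower. In all, 74 of 12150 features differed, 45 higher and 29 lower at day 22. Fitted on these 8 arrays alone the count was 16, and a term for replicates 1 and 2 against 3 and 4, added after seeing the data, raised it to 144. The arrays of replicates 1 and 2 alone gave 24, and replicates 3 and 4 alone gave 50. Of the 74 features, 51 had 1 gene symbol. The 22 spots listed under several genes that include a hemoglobin gene were kept as separate features. Hemoglobin spots had a mean of 0.50 at day 21 and 1.24 at day 22. A single hemoglobin signal may therefore lie behind several of the 45 higher features, and its share was not counted.

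At day 35, 131 of 12247 features differed from day 21, 88 higher and 43 lower. Prnd was higher by 1.84 ± 0.19 (SE), Cd93 by 1.25 ± 0.31, Hbb-b1 by 1.12, Got2 by 1.11 and the imprinted gene Peg3 by 1.03. The 2 spots of Peg3 had hypoxia means of 0.05 and 0.37. Arntl was lower by -1.53 ± 0.29, Cdk19 by -1.51 ± 0.11, Spon2 by -1.07, Mfap4 by -0.95 and S100a9 by -0.93. Fitted on these 8 arrays alone the count was 83, and with the term for the replicate pairs it was 237. Fitted alone, replicates 1 and 2 gave 55, and replicates 3 and 4 alone gave 94. Of the 131 features, 85 had 1 gene symbol. Hemoglobin spots had a mean of 0.50 at day 21 and 1.55 at day 35. Those with several symbols were kept as separate features, so a single signal may lie behind several of the 88 higher features.

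Neither phase showed a gene with a trend on log2 day that passed limma's adjusted threshold among 12159. At an unadjusted p under 0.05 there were 333 genes in the hypoxia phase and 164 in recovery. The lowest p values in hypoxia belonged to Mmp2, a matrix protease, with day means from -0.05 at day 1 to 0.94 at day 14, and Wfdc1, from -0.14 to 0.83. In the other direction were Agr2, from 1.19 at day 1 to 0.04 at day 21, and Lgals1, from 1.17 to 0.29. Of the 3 Agr2 spots, 1 had a hypoxia mean of -0.02, against 0.50 and 0.52. In recovery, the chaperone genes Dnajb1 (-0.30 at day 22 and 0.76 at day 35) and Bag3 (-0.07 and 0.67), and Znrd2 (0.65 and -0.24) and Arntl (1.09 and -0.01) came first. With all 36 arrays and the day as a random block, 14 genes in hypoxia and 9 in recovery passed.

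At single days the p-values cover the spread between arrays alone, since the labels name a single pool per condition and day. The highest and lowest given here are among genes with 1 symbol and a single sign on all arrays of the day. At day 1 Cdk19 (1.57), Hbb-b1 (1.25) and Phtf1 (1.203) led the rise and Tgfbr3 (-1.40), Igfbp3 (-1.32) and Prelp (-1.16) the fall. At day 3 Mfap4 (1.67), the neutrophil granule gene Ltf (1.51) and Cdk19 (1.498) were highest, and S100a9 (-2.63), Pdlim7 (-1.43) and Tgfbr3 (-1.40) lowest. At day 7 Cdk19 (1.95), Hbb-b1 (1.63) and Phtf1 (1.63) were highest and Pdlim7 (-2.12), Irgq (-1.91) and Ttc12 (-1.83) lowest. At day 14 Cdk19 (1.60), Arntl (1.55) and Mfap4 (1.43) were highest, and S100a9 (-2.72), the metallothionein gene Mt2 (-2.16) and Cd93 (-2.002) lowest. At day 21 Cdk19 (1.79), Arntl (1.52) and Mfap4 (1.37) were highest, and S100a9 (-2.32), Cd93 (-1.02) and Tgfbr3 (-0.92) lowest.

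After return, day 22 had Hbb-b1 (1.31), Prnd (1.29) and Phtf1 (1.23) highest and the clock genes Nr1d2 (-0.75), Tef (-0.72) and Per3 (-0.65) lowest. Day 24 had Cttnbp2 (0.50), AU040972 (0.47) and Gas6 (0.45) highest and Cd93 (-0.95), F2r (-0.92) and Tgfbr3 (-0.84) lowest. At day 28 the cold-inducible gene Cirbp (0.83), Hmcn1 (0.82) and Rpl39 (0.71) were highest, and S100a9 (-2.97), Neat1 (-1.62) and the interferon-inducible gene Tgtp1 (-1.56) lowest. At day 35 Prnd (2.18), Hbb-b1 (1.64) and Phtf1 (1.495) were highest, and S100a9 (-3.25), Stfa1 (-2.09) and the platelet gene Ppbp (-0.81) lowest.

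The number of features called was 2421 at day 1, 2840 at day 3, 4345 at day 7, 3389 at day 14 and 557 at day 21. It was 192 at day 22, 354 at day 24, 3938 at day 28 and 394 at day 35. With 1 array of the day left out these became 90 to 155, 79 to 141, 2164 to 3733 and 232 to 264. Fitted on the arrays of the day alone, day 3 had 103, day 7 had 1961, day 14 had 566, day 21 had 47, day 22 had 66 and day 24 had 1350. Scaling the arrays to a common spread gave 239 higher and 377 lower at day 22 against 99 and 93, 1165 and 1222 at day 24 against 93 and 261, and 634 and 732 at day 35 against 225 and 169. Requiring a 1.5-fold change turned the balance at days 1, 3, 7, 14 and 28 toward lower features, with 176 higher and 436 lower at day 7 and 39 and 350 at day 28. It moved days 22 and 35 the other way, to 56 higher and 9 lower and to 79 and 15, and left 1 and 35 at day 24. Hemoglobin spots with several symbols, each a separate feature, may be among the higher ones at days 22 and 35 and were not counted apart. Median centring gave 1151 higher and 1208 lower at day 1, against 1304 and 1117, and 1956 and 1957 at day 28. Among 189 tests of a list at a day, 68 passed with the preset correlation, 35 higher and 33 lower, and 22 of 153 passed with an estimated correlation. The latter used only members with a value on all arrays: 22 pulmonary hypertension candidates, 27 cell cycle genes and 8 smooth muscle genes. For pulmonary hypertension candidates the estimate was 0.0035, below the preset 0.01, so there it was not the stricter test. With an estimated correlation, pulmonary hypertension candidates were lower at days 1, 3, 7, 14, 21 and 24 (adjusted p = 0.014, 0.043, 0.0094, 0.020, 0.033 and 0.020; at day 21 the preset correlation gave adjusted p = 0.061). Cell cycle genes were higher at days 3, 7, 21 and 35 (adjusted p = 0.014, 0.020, 0.041 and 0.0094 with an estimated correlation). Smooth muscle genes were higher at day 3 (adjusted p = 0.041), extracellular matrix genes at day 21 (adjusted p = 0.039), and airway genes lower at day 35 (adjusted p = 0.020), each with an estimated correlation. The estimates at single days come from differences between arrays of a day, so they hold no co-movement from pool to pool. They were 0.050 for cell cycle, 0.15 for smooth muscle and 0.23 for extracellular matrix genes, against 0.32, 0.47 and 0.22 over the phases. For pulmonary hypertension candidates and airway genes they were 0.0035 and 0.077, against 0.072 and 0.16.

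**Figure D3:**
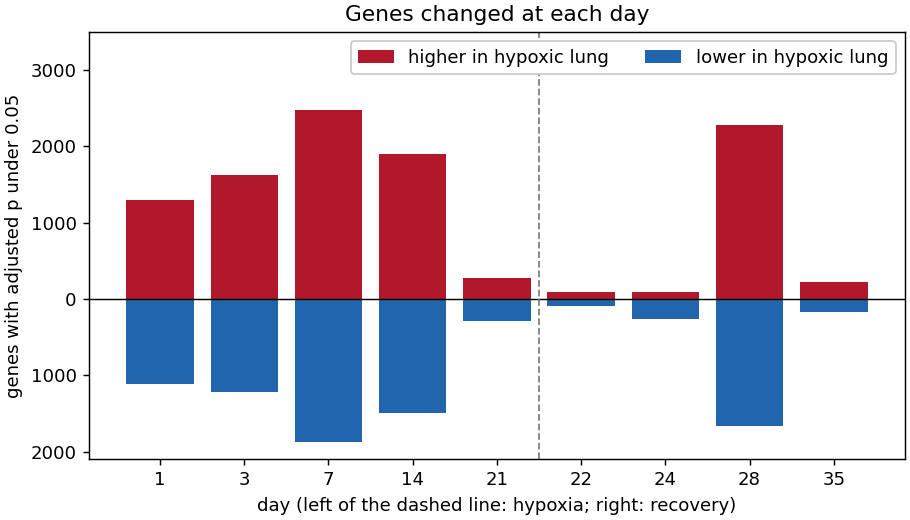
Number of genes or unnamed spots with a limma adjusted p under 0.05 at each day, higher in hypoxic lung above 0 (red) and lower below 0 (blue), from 4 arrays a day. Day 7 has 2471 higher and 1874 lower, and day 28, 7 days into recovery, has 2278 and 1660; with a 1.5-fold change required, lower features outnumber higher ones at both days.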

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

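No test in this part was chosen only after its result was seen. Of 78 groups of arrays or time points examined, 5 held a value far from the others of its group, and chance picks about 1 in 20 groups. The SD of the log2 ratios was 0.350 on replicate 4 of day 1, against 0.267 to 0.281 on the other arrays of that day. On replicate 2 of day 7 it was 0.482, against 0.396 to 0.406. Mfap4, the elastic fibre protein, stood at 0.17 at day 1 and between 1.37 and 1.67 at the other hypoxia days. Nr1d2, a clock repressor, was lowest at day 7 (-1.70), with the other hypoxia days between -1.06 and -0.84. Aldh1b1, a mitochondrial aldehyde dehydrogenase, was lowest at day 28 (-0.97), with the other recovery days between -0.48 and -0.42.

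Hypoxia and recovery differed by a direct test in 4 genes: Cdk19 (1.63), Mest (0.79), Mfge8 (0.64) and Alpl (0.58), each higher in hypoxia. As lists with the preset correlation, smooth muscle contractile (adjusted p = 1.69e-08), glycolysis and extracellular matrix (both adjusted p = 0.000166) and cell cycle genes (adjusted p = 0.000843) were higher in hypoxia than in recovery, each with adjusted p = 0.73 with an estimated correlation. Pulmonary hypertension candidates (adjusted p = 0.0102) and oxidative phosphorylation genes (adjusted p = 0.022) were lower, with adjusted p = 0.73 and adjusted p = 0.78 with an estimated correlation. Of 100 splits of the 9 time points into 5 and 4, run out of 126 possible ones, 4 gave at least 4 genes, the real split included. That share is below 0.05, but it does not exclude chance. The other splits among these gave 15, 71 and 1013 genes, more than the real one. The real count itself falls to 1 without day 3, 22, 24 or 28. The highest other split gave 1013 genes. It put day 28 with days 1, 3, 7 and 14 and placed day 21 with days 22, 24 and 35, which points to a structure of the time points that the phases do not follow. The first of these sets holds the days whose means spread widely over features (SD 0.23, 0.24, 0.31, 0.28 and 0.28 at days 1, 3, 7, 14 and 28) and the other the narrow ones (0.16, 0.14, 0.15 and 0.16 at days 21, 22, 24 and 35). Some genes do not follow that split: Cdk19 was at 1.79 at day 21 and -0.15 at day 28, Arntl at 1.52 and -0.02, and Mest at 0.60 and -0.35.

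Day 22 differed from day 21 in 74 features and day 35 differed from day 21 in 131. Among the 35 splits of the 8 arrays, 1 gave as many in each case, the real one, and the highest other counts were 3 and 1. These splits treat the arrays as exchangeable, but arrays of a replicate pair were alike. At days 21, 22 and 35 the median r was 0.58, 0.64 and 0.72 within the pairs and -0.04, -0.15 and 0.26 across them. Splits that keep the pairs balanced are fewer and were not counted apart, so a chance division of these arrays is not excluded. Since the labels name a single pool per condition and day, the splits say nothing of chance differences between the pools. The genes behind these counts include S100a9, Cdk19 and Prnd, whose values are given with the comparison of those days. Hemoglobin spots with several symbols, which moved together, may also lie behind part of these counts.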

How the results depend on the processing

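The fits on replicates 1 and 2 alone or 3 and 4 alone, and those with a term for these pairs, were tests chosen after the results were seen, and the other alternatives were planned. Genes over the hypoxia phase kept within 1.5 times their count of 5152 under the 9 other planned settings and ranged from 3999 to 5459 with a time point left out. For single genes, planned settings gave 5534 values with the same call, 316 that lost and 181 that gained it, and 0 that reversed, whereas the added ones gave 918, 54, 78 and 3. The 3 reversals came from replicates 3 and 4 alone over the hypoxia phase, with Dnah5 at 0.10, Cxcl1 at 0.023 and Tnnt1 at -0.052; the cause was not tested.

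Scaling all arrays to a common spread moved the counts to 1863 at day 3, 2628 at day 7, 1993 at day 14, 974 at day 21, 616 at day 22, 2387 at day 24 and 1366 at day 35. It gave 131 features between days 22 and 21, 406 between days 35 and 21, 3155 in recovery and 10 between phases (8 higher and 2 lower, against 4 and 0). Requiring a 1.5-fold change, which lowers a count by construction, left 242, 264, 612, 443, 65, 65, 36, 389 and 94 features at days 1, 3, 7, 14, 21, 22, 24, 28 and 35, and 42 and 70 between days 22 or 35 and 21. On the arrays of the day or days alone, with fewer arrays behind each spread, the counts were 103, 1961, 566, 47, 66 and 1350 at days 3, 7, 14, 21, 22 and 24, and 16 and 83 for the differences from day 21. Other causes in this part were not tested.

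Replicate numbers were not taken to pair the arrays: 126 of 144 pairs of same-numbered arrays from different days had deviations correlated over 0.1, but the lowest pair was at -0.15, and 15 of 36 arrays correlated best with their own number. The arrays shared a pair of numbers rather than a number, with a median r of 0.38 for the same number, 0.40 for 1 with 2 or 3 with 4, and -0.40 between these pairs. The replicate number as a block gave 976 features at day 21, 342 at day 22, 771 at day 24, 600 at day 35, and 140 and 221 for days 22 and 35 against 21. A block of replicates 1 and 2 against 3 and 4 gave 1045, 372, 845, 641, 144 and 237 for the same results. Replicates 1 and 2 alone gave 949 at day 1, 556 at day 22, 126 at day 24, 251 at day 35, 24 and 55 for the differences from day 21, 1103 in recovery and 34 between phases. Replicates 3 and 4 alone gave 1376 at day 21, 871 at day 22, 80 at day 24, 645 at day 35, 1609 in recovery and 2 between phases.

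All 36 arrays with the day as a random block gave 2475 features in recovery, 800 between phases, and 14 and 9 with a trend in hypoxia and in recovery. With the replicate block added these were 2545, 816, 16 and 11, and with the block of replicate pairs 2595, 849, 16 and 12. The difference between phases was 8 both for genes with a value on all 36 arrays and with robust eBayes. Each spot on its own gave 897 in recovery and 1 trend in hypoxia, the median of a day's arrays gave 255 in recovery, and recovery from day 24 on gave 12, with 1 gene between phases. No list over the phases passed with an estimated correlation (0 of 63 tests with limma's camera, 1 at an unadjusted p under 0.05, against 12). At single days, where the estimate covers only the spread between arrays, 22 list tests passed with an estimated correlation and 43 in a rank test, against 68.

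Leaving out an array gave 1378 to 2007 at day 1, 2140 to 2511 at day 3, 3440 to 3941 at day 7, 2373 to 3314 at day 14, 259 to 481 at day 21, 90 to 155 at day 22, 79 to 141 at day 24, 2164 to 3733 at day 28 and 232 to 264 at day 35. Day 22 against 21 ranged from 48 to 73 and day 35 against 21 from 93 to 116. The arrays that moved a count by over 1.5 times were replicates 3 (1516) and 4 (1378) of day 1, replicates 1 (265), 2 (335) and 4 (259) of day 21, replicates 1 (90) and 2 (111) of day 22, replicates 1 to 4 of day 24 (110, 79, 141 and 141), replicate 1 of day 28 (2164) and replicates 2 (232) and 4 (255) of day 35. Without replicate 2 of day 21, day 22 against 21 had 48.

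Leaving out a time point gave 0 to 678 features in recovery, 1 to 124 between phases, 0 to 1 for each trend, 10 to 19 lists over the phases and 58 to 64 list tests at single days (69 without replicate 1 of day 28, added after seeing the data). Recovery had 340 without day 1, 13 without day 3, 376 without day 14, 12 without day 22, 0 without day 24 (limma; 2423 at an unadjusted p under 0.05) and 2 without day 28. The difference between phases had 14 without day 1, 1 without day 3, 22, 24 or 28, 2 without day 7 and 124 without day 21. A trend appeared in 1 gene in hypoxia without day 21 and in 1 in recovery without day 35, and 19 lists passed without day 24. Where the count of trends was 0 with a time point left out, limma gave 239 to 457 genes in hypoxia and 98 to 201 in recovery at an unadjusted p under 0.05. Spots near background limit the precision of a log2 ratio, and since the intensities were not used here, which genes this concerns stays open.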

Other observations

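The tests of the replicate pairs, of day 28 without an array, of days 22 and 35 array by array, and of the hemoglobin spots were chosen after the results were seen, and the tests of the mean ratio over all recovery days and of gene length were not. Genes of the interferon response fell at day 28 alone among the 9 days, with a list median of -0.74 and 4 of 7 members lower (cameraPR adjusted p = 4.7e-07), and the interferon-inducible gene Tgtp1 stood at -1.56 there against -0.33 to 0.25 at the other days. Replicate 1 of day 28 had an SD of 0.52 against 0.24 to 0.33 on the other arrays of that day, and without it 2164 features were called there instead of 3938. Without it the interferon list (median -0.64, 4 of 7 lower; adjusted p = 4.3e-08), the chaperones (median -0.32, 14 of 23 lower; adjusted p = 7.7e-10, or adjusted p = 0.046 with an estimated correlation) and the macrophage list (median -0.44, 5 of 9 lower; adjusted p = 2.8e-05, or adjusted p = 0.0068 with an estimated correlation) were still lower at day 28. An estimated correlation was not run for the interferon list, since fewer than 5 members had values on all arrays. Chaperone genes fell as a list at day 22 (median -0.22, 9 of 23 lower; adjusted p = 0.012 with an estimated correlation) and at days 24 (median -0.13, 8 of 23 lower; adjusted p = 6.3e-05) and 28 (median -0.37, 16 of 23 lower; adjusted p = 3.1e-10), where the estimated correlation gave adjusted p = 0.20 and 0.086. The same list was shifted up at day 14 (median 0.12, 10 higher and 4 lower; adjusted p = 0.0017, or adjusted p = 0.39 with an estimated correlation) and at day 35 (median 0.06, 8 higher and 1 lower; adjusted p = 6.1e-16, or adjusted p = 0.084 with an estimated correlation). Hspa4l stood at -1.13 and Hsp90b1 at -0.97 at day 28. Macrophage and monocyte genes fell as a list at days 1, 3, 14, 21 and 28, with medians of -0.22, -0.18, -0.12, -0.14 and -0.50 and 3, 4, 4, 3 and 5 of 9 lower. The estimated correlation was run on the 5 of 9 members with a value on all arrays. With it these days had adjusted p = 0.24, 0.020, 0.041, 0.014 and 0.017, and day 35 had adjusted p = 0.020 against 0.070 with the preset correlation. With all arrays in, it was likewise run on 21 chaperone, 12 immediate early and 10 erythroid genes, fewer than the medians and counts cover. Neutrophil genes changed direction between days: the list was higher at days 1, 7 and 22 (adjusted p = 0.0098, 0.031 and 0.021; 3 of 5, 3 of 5 and 1 of 6 higher) and lower at days 14, 21, 28 and 35. There the adjusted p was 0.00024, 3.2e-13, 3.3e-08 and 5.6e-27, the last the lowest of the 189 list tests, with 4 of 6, 1 of 6, 2 of 5 and 4 of 6 lower and S100a9 at -2.72, -2.32, -2.97 and -3.25. An estimated correlation was not run for this list either. On the first day after return, endothelial genes fell (median -0.19, 2 of 7 lower; adjusted p = 0.020 with an estimated correlation), with Ednrb at -0.60. Immediate early genes rose on that day (median 0.10, 4 of 14 higher; adjusted p = 0.014 with an estimated correlation), with Atf3 at 0.84. With the preset correlation that list was lower at days 3 (0 higher, 6 lower), 14 (0 higher, 8 lower) and 24 (2 higher, 3 lower) and higher at day 35 (4 higher, 1 lower), at adjusted p = 0.0033, 0.0050, 0.013 and 0.0077. The estimated correlation gave adjusted p = 0.091, 0.11, 0.37 and 0.16 at these days. Erythroid genes were higher at day 22 (median 0.10, 4 of 15 higher; adjusted p = 0.0034 with an estimated correlation), with Hbb-b1 at 1.31. They were also higher at days 1, 3, 7, 14 and 35 with the preset correlation (adjusted p = 0.00019, 0.025, 8.5e-05, 0.049 and 1.4e-10), where the estimated correlation gave adjusted p = 0.25, 0.26, 0.15, 0.26 and 0.076. For the erythroid list the estimate was -0.043, below the preset 0.01, so it was not a stricter setting. The list median at day 35 was 0.02, and the hemoglobin members may share 1 signal. Differences between these days were not tested.

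Some genes swung between neighbouring days. S100a9 stood at 0.31 at day 1, -2.63 at day 3, -0.19 at day 7 and -2.72 at day 14, and in recovery at 0.19 at day 22 and -3.25 at day 35. Ltf, a neutrophil granule gene of the same list, stood at 1.51 at day 3, where S100a9 was low, and at 1.24 at day 7. The metallothionein gene Mt2 was between 0.50 and 1.04 at the other hypoxia days and at -2.16 at day 14. Arntl stood at 1.09 at day 22, 0.59 at day 24 and -0.02 at day 28, and Nr1d2 at -0.75, -0.38 and -0.13. Prnd was at 0.34 at day 21, 1.29 at day 22, 0.22 at day 24 and 2.18 at day 35.

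Hemoglobin spots, 29 in all, moved together from pool to pool, with means of 1.27, 0.73, 1.49, 0.90, 0.50, 1.24, 0.17, -0.56 and 1.55 over the 9 days. They followed the mean of 12 other erythroid genes (Pearson r = 0.758, exact permutation p = 0.0166; Spearman rho = 0.65, exact permutation p = 0.0666), with r = 0.733 (exact p = 0.0231) in replicates 1 and 2 and 0.686 (exact p = 0.0403) in 3 and 4, and it rested partly on days 28 and 24, without which r was 0.523. Red cell RNA that differed between pools may therefore contribute, although the 12 genes were divided. Alas2 (r = 0.953), Rhd (0.879) and Slc4a1 (0.772) followed the hemoglobin spots closely. Bpgm (0.543), Car1 (0.402) and Gata1 (0.276) did so less. Tfrc (0.067), Urod (-0.003), Ermap (-0.113), Cpox (-0.240), Fech (-0.267) and Alad (-0.303) did not follow them. A difference between the phases stays open. The hypoxia mean of 0.98 ± 0.40 (SD, n = 5) and the recovery mean of 0.60 ± 0.98 (n = 4) could not be separated (exact permutation p = 0.484 over 126 splits). That comparison does not test length of exposure. Within the hypoxia phase the slopes on log2 day were -0.10 ± 0.18 (SE) for Hbb-b1 and -0.14 ± 0.14 for Hba-x. Neither passed the limma threshold, so length of exposure also stays open. Spots named Phtf1, Got2, Tia1, Vim, Rhbdd3 and Cd200 followed the hemoglobin spots at r of 0.953 to 0.995, whereas the 3 other spots of Tia1 and Rhbdd3 had a median r of -0.182, so hemoglobin sequence on those spots is a candidate explanation.

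Genes off 0 over the hypoxia phase tended to stay off 0 in recovery: 2109 genes picked at days 1, 7 and 21 kept a mean share of 0.545 ± 0.372 (SD over 4 recovery days) of their size at days 3 and 14. Taking out the trend with gene length left 2641 (89.6 percent) of 2949 hypoxia-phase calls with 1 symbol and a length past the threshold. This argues against such a trend as the whole cause of those calls, although genes that rose had a shorter median span (17.9 kb) than genes that fell (35.1 kb). The share kept in recovery was not computed again without the trend, so length as its cause stays open. A constant bias of each gene as the whole cause is argued against at days 22 and 35, where no array kept a share above 0.456. A smaller constant bias, added to an effect of the hypoxia, is not excluded there, since no array of these days was below a share of 0.208. Over all recovery days a constant bias stays open, with a share of 1.08 at day 28 against 0.295, 0.532 and 0.278 at days 22, 24 and 35. Replicate 1 of day 28 was at 1.72, against 0.77 to 0.92 on the others, and without it day 28 was still at 0.861. The mean share then fell to 0.491 ± 0.272, and mean plus SD went from 0.917 to 0.764. That is below the 0.8 set beforehand as the bound against a constant bias. Since the array was left out after the results were seen, this does not decide the question. A lasting effect of the hypoxia, which the design names, stays open and was not tested.

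Replicates 1 and 2 differed from replicates 3 and 4 in a way that recurred: the difference between the pairs correlated across genes between all 36 pairs of days, with a median r of 0.582. Different mice in the pairs would differ from day to day, and this recurrence argues against them as the whole cause. An effect of labelling or dye on each gene that runs opposite ways in the pairs may account for it, but no label records the dye of an array. If that is so, averaging all 4 arrays of a day would offset it, and a fit on either pair alone would not. No biological explanation was tested, since the labels give the pairs no meaning.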
